A study of Homo sapiens with 60 samples.

How the data were processed

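RNA from SW1783 cells grown in Leibovitz L-15 medium with 10% fetal bovine serum was sequenced 24 h after treatment in 60 libraries, 3 per group. Per the labels, RNA with an integrity number above 7 went into directional libraries that were read as 100 bp pairs on an MGI sequencer. The sample labels give the vehicle as 0.1% DMSO and the series design text as 2%, and the deposited values cannot settle which was used. A DMSO content of the treated groups is not recorded here, so a solvent difference from the vehicle cannot be told apart from treatment. Whether the 3 replicates of a group were separate cultures is not given in the sources used here, so the p-values may measure technical spread alone. The titles of all 60 libraries name BatchA and a second sequencing, which leaves this open. LY294002, thioridazine and the ethanol extracts named in the series design were not analysed here.

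The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the human build GRCh38. Their parameters, the annotation release and the strand setting are not given in the sources used here. The deposited table holds expected counts from RSEM for 60675 Ensembl genes and 60 libraries, not scaled for depth. Of its values 90.5% were whole numbers when printed to 2 decimals, and rounding all values to whole counts changed a library's total by at most 0.0002%. All 60 columns were matched to a library by its description code. Library totals were 20.2 to 32.8 M. A gene with 0 counts in a library could have up to 3 counts, which is 0.091 to 0.149 CPM; floors of this kind cover counting error only. Symbols came from a table of gene names for 56558 genes and from GENCODE v29 for 497 more, coordinates from GENCODE v29, and 3620 genes kept only their identifier. Of 60 pairs of replicates none was identical, and the chi-square per gene between replicates was 1.63 to 5.93, where counting error alone gives about 1.

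Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 20 groups, which left 17569 of 37383 genes with any count, and libraries were scaled by TMM, with factors from 0.80 to 1.04. A quasi-likelihood model was fitted to all 60 libraries with 1 mean per group and 40 residual degrees of freedom, and each comparison was tested two-sided by edgeR's quasi-likelihood F test. Adjusted p are Benjamini-Hochberg values over the 17569 genes of a comparison, and genes under 0.05 are called changed. The common dispersion corresponds to a biological coefficient of variation of 3.2%. CPM values of single tested genes use the TMM factors. The CPM of the floor, of untested immune markers and of the summed mitochondrial ribosomal RNA are over library totals without those factors. Fold changes are on the log2 scale with their SE, and spreads between libraries are SD. The 28 comparisons are 19 against the vehicle, 6 of high against low dose and 3 of dried against fresh ginger.

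Before the data were examined, 32 gene lists with 803 genes, 30 single genes, the comparisons, tests and alternatives were chosen. Lists with at least 5 tested members, 31 in all, were tested with limma 3.58.1 camera on voom values at a preset correlation of 0.01 between genes, adjusted over the 31 lists of a comparison, and again with an estimated correlation. Of 388 list calls 224 held with the estimated correlation, and each list called below also passes with it unless its p is given. The rule for named genes, chosen at the same time, took in wortmannin, each high dose and dried against fresh ginger at the high dose the 5 largest rises and falls among called genes with a mean log2 CPM of at least 1, a symbol and groups that do not overlap. It added up to 4 called members with the smallest p from each list that had 3 called members or passed its test, and the 30 single genes in any comparison. At other doses only those genes are named.

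The procedure was tested on counts simulated from the vehicle means and fitted dispersions, of which 17020 genes passed the filter, with known changes in the wortmannin group. Of 50 changed genes at each size it recovered 26 at 1.2-fold, 46 at 1.5-fold, 48 at 2-fold and 50 at 4-fold, with 5 false calls among 196, and it called 1 of 31 lists, the shifted one. To see whether replicate numbers pair libraries across groups, residuals were correlated. The mean was 0.02 for libraries with the same number and -0.01 for others. Residuals cancel out within a group, so these means are not independent. Of 60 libraries 31 correlated best with their own number, where about 1 in 3 would without pairing, so weak pairing stays possible. A block for replicate number raised the count of called genes in every comparison, from 6418 to 6511 under wortmannin and from 25 to 81 under low-dose Pinellia. This goes with such a pairing, which the reported fit leaves out. In 1 of the 28 comparisons, fresh ginger at the medium dose against the vehicle, every pair correlated above 0.1, and its blocked count is given. Because all comparisons with wortmannin share the vehicle, 8 simulations of unchanged groups gave the correlation and covariance that sharing alone produces. The 3 vehicle libraries were not split into separate controls, so part of any excess of covariance over the simulated value may come from the shared libraries. Comparisons of high against low dose share no library with wortmannin or the vehicle, but were not correlated with wortmannin.

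Alternatives were RLE size factors, no filter, a stricter filter (1 CPM in at least 3 libraries), a block for replicate number, a fit with only the 2 groups compared, DESeq2 1.42.0 (with a local dispersion fit in place of the parametric one) and leaving out each library in turn. RLE factors moved the median log2 fold change of all genes by at most 0.021. Both scalings assume that most genes do not change or change evenly in both directions, so their agreement cannot check that assumption. At the high doses 75.2% of tested genes were called under Coptis and 58.8% under Scutellaria, so the direction of small changes there is relative to the scaling. Leaving out mitochondrial genes, taking out a trend with exon length and the block with only 2 groups were added after the data had been seen. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.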

Results

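SW1783, an established human astrocytoma cell line, was profiled by RNA sequencing after 24 h of treatment. The treatments were water extracts of 6 herbs used in East Asian medicine and wortmannin, an inhibitor of phosphoinositide 3-kinase (PI3K) that served as the positive control. The stated purpose of the series was to describe digestive herbs by the transcriptomes they induce in cells. The extracts were made from fresh ginger rhizome, dried ginger rhizome, Pinellia tuber, Scutellaria root, Coptis rhizome and jujube fruit. Each extract was used at 3 doses, each 5 times the next lower. The high dose was 500 µg/mL for both gingers, Pinellia and jujube, 410 µg/mL for Scutellaria and 20 µg/mL for Coptis, and wortmannin was used at 10 µM. High doses below 500 µg/mL were, per the labels, those that inhibit 20% of growth. With the vehicle, dimethyl sulfoxide (DMSO), this made 20 groups of 3 libraries and 60 libraries. Library totals were between 20.2 and 32.8 M counts, with a median of 25.4 M. Of 60675 annotated genes, 17569 had enough counts to be tested.

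Each treatment was compared with the vehicle, each high dose with the low dose of the same extract, and dried with fresh ginger at each dose, which made 28 comparisons. Genes responded most to Coptis and Scutellaria, as the plot of called genes by dose shows. At the high doses 13207 genes were called under Coptis, 10336 under Scutellaria, 3393 under fresh ginger, 3168 under Pinellia, 3035 under jujube and 2981 under dried ginger. Wortmannin gave 6418. Most changes were small: the median absolute log2 fold change of the called genes was 0.70 under the high dose of Coptis, 0.41 under Scutellaria and between 0.20 and 0.25 under wortmannin and the other 4 high doses. The single genes named below as risen or fallen had all 3 libraries of the treated group on 1 side of the 3 libraries they were compared with, a separation that chance gives for 10% of genes. List members counted as risen or fallen needed only to pass the test. Large rises and falls of single genes are given among called genes with a mean log2 CPM of at least 1 and groups that do not overlap. The first number of each library's description code was not shared between the vehicle and any extract, so a difference between code sets cannot be told apart from treatment in the comparisons with the vehicle. The high and low doses of an extract, and fresh and dried ginger, share that number. The code starts with A1 for the vehicle and with 1 for wortmannin, and whether these are the same set is not known. Wortmannin has no second dose for a check within a set.

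**Figure D1:**
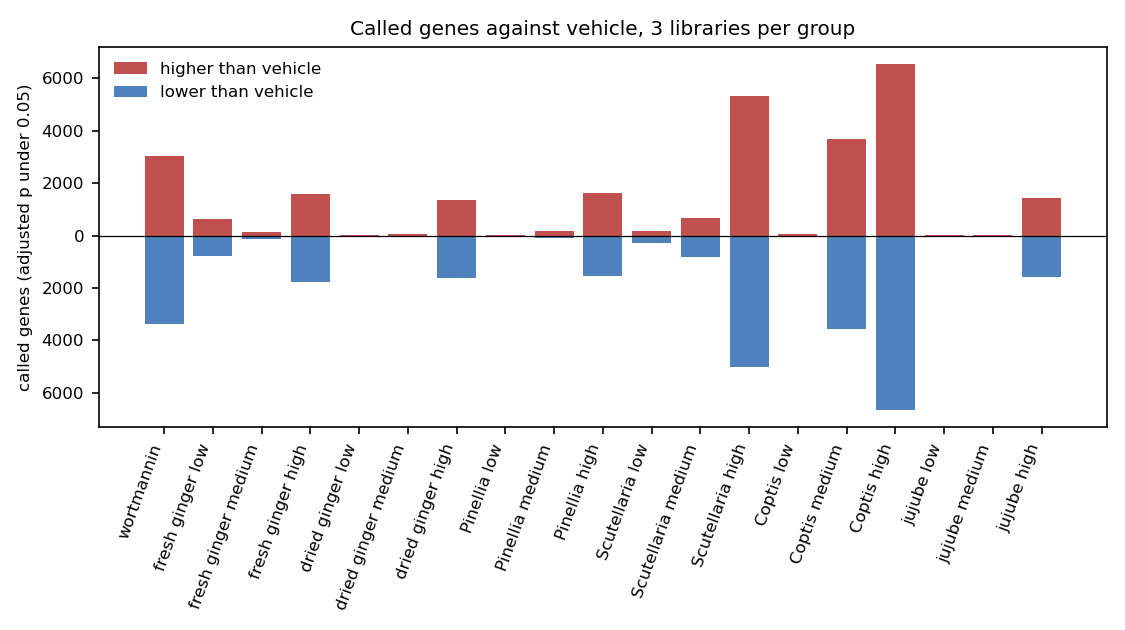
Number of genes called at an adjusted p under 0.05 (vertical axis) higher (upward bars) and lower (downward bars) than in the vehicle, for wortmannin and each dose of the 6 extracts (horizontal axis), with 3 libraries per group. The high dose of Coptis gave 6540 higher and 6667 lower genes, and fresh ginger gave more genes at its low dose (1395) than at its medium dose (263).

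Under wortmannin the genes of cell division and ribosome production were lower, and genes that PI3K signalling holds down through the FOXO transcription factors were higher. All 35 tested genes of G2 and mitosis fell (35 adjusted over the list alone), with a median log2 fold change of -0.37 (adjusted p = 1.3e-26). Of 36 genes of DNA replication, 35 fell (36 adjusted over the list alone; median -0.47, adjusted p = 1.7e-32), among them RRM2, which makes deoxynucleotides (-0.70 ± 0.03, adjusted p = 6.1e-23). MYBL2, a transcription factor of the cell cycle, fell by a log2 of 1.03 ± 0.06 (SE). Of 33 MYC and ribosome biogenesis genes, 31 fell (31 adjusted over the list alone; median -0.28, adjusted p = 2.0e-19). Of 28 FOXO targets, 17 rose and 3 fell (21 and 3 adjusted over the list alone; median 0.20, adjusted p = 6.7e-07). IGFBP1, a binding protein of insulin-like growth factors (ENSG00000146678, GRCh38 chromosome 7, 45888357 to 45893668), rose from 22.8 ± 1.03 to 69.7 ± 3.17 CPM (counts scaled to the library total; mean ± SD, n = 3), a log2 fold change of 1.61 ± 0.05 (SE; adjusted p = 1.8e-29). KLHL24 (0.92 ± 0.05), TXNIP (0.78 ± 0.08) and IRS2 (0.63 ± 0.08), an adaptor of the insulin receptor, also rose. Autophagy and lysosome genes rose in 15 of 31 cases and fell in 3 (15 and 5 adjusted over the list alone, list test adjusted p = 9.2e-04), with the cathepsin CTSB at 0.49 ± 0.03. Of 11 tubulin genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone, list test adjusted p = 6.4e-07). CRABP2, a carrier of retinoic acid (-1.71 ± 0.11, adjusted p = 2.9e-18), and the chemokine CXCL12 (-1.19 ± 0.08) fell as well. In all, 3038 genes were higher and 3380 lower. With a trend in exon length taken out, 3351 were higher and 3150 lower.

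Fresh ginger at its high dose raised genes of the amino acid and integrated stress response, of endoplasmic reticulum folding and of oxidative and xenobiotic defence. Genes of sterol synthesis, DNA replication and the actin cytoskeleton were lower. Of 35 targets of ATF4, the transcription factor of that stress response, 33 rose (34 adjusted over the list alone), with a median log2 fold change of 0.56 (adjusted p = 8.1e-82). ASNS, which makes asparagine (ENSG00000070669, chromosome 7, 97852118 to 97872542), rose from 49.2 ± 0.398 to 119.8 ± 2.68 CPM (mean ± SD, n = 3), a log2 fold change of 1.28 ± 0.03 (SE; adjusted p = 7.5e-36). ADM2 (1.97 ± 0.14), GDF15 (1.89 ± 0.10), CHAC1 (1.77 ± 0.10), TRIB3 (1.38 ± 0.05) and CBS (1.35 ± 0.08) had the largest rises among genes with a mean log2 CPM of at least 1. Of 24 genes of endoplasmic reticulum folding, 20 rose (22 adjusted over the list alone, list test adjusted p = 4.1e-33), including HERPUD1 (0.92 ± 0.04) and the chaperone HSPA5 (0.49 ± 0.03). Of 29 targets of NRF2, which drives oxidative defence, 23 rose (23 adjusted over the list alone, list test adjusted p = 2.0e-28), including NQO1 (0.79 ± 0.03). Of 12 targets of the aryl hydrocarbon receptor, a sensor of plant and environmental compounds, 9 rose (9 adjusted over the list alone, list test adjusted p = 7.8e-21), with CYP1B1 at 0.66 ± 0.04. Hypoxia and glycolysis genes rose in 23 of 37 cases (25 adjusted over the list alone, list test adjusted p = 1.2e-18), with NDRG1 at 1.03 ± 0.05. Falls took in 18 of 25 cytoskeletal targets of YAP and SRF (22 adjusted over the list alone, list test adjusted p = 3.3e-22; ACTA2 -0.64 ± 0.04), 27 of 36 replication genes (34 adjusted over the list alone, list test adjusted p = 3.3e-22) and 17 of 26 cholesterol genes (19 adjusted over the list alone, list test adjusted p = 3.7e-11, with 1 risen). LGR6, a receptor of R-spondins, fell as well (-1.54 ± 0.16). The high dose gave 1603 higher and 1790 lower genes, and 4090 genes differed from the low dose, ASNS by 1.24 ± 0.03 and ACTA2 by -0.72 ± 0.04.

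At the medium dose of fresh ginger several of these lists were higher, with smaller medians. Of 35 ATF4 targets 21 rose (28 rose and 1 fell adjusted over the list alone; median 0.25, adjusted p = 1.7e-48), with ASNS at 0.30 ± 0.03. Folding genes rose in 14 of 24 cases (15 adjusted over the list alone, list test adjusted p = 1.6e-36), with HSPA5 at 0.44 ± 0.03 (adjusted p = 5.2e-18). Hypoxia and glycolysis genes rose in 18 of 37 (30 adjusted over the list alone, list test adjusted p = 3.9e-45), with NDRG1, which hypoxia induces, at 0.57 ± 0.05. Of those 37, 16 rose at the low dose (21 adjusted over the list alone, list test adjusted p = 5.3e-16), NDRG1 by 0.46 ± 0.05 and the lipase inhibitor ANGPTL4 by 0.38 ± 0.06. ATF4 targets rose in 8 cases and fell in 2 (11 and 2 adjusted over the list alone, list test adjusted p = 1.7e-04). Cytosolic ribosomal proteins rose in 13 of 61 cases at the low dose (14 adjusted over the list alone; median 0.11; adjusted p = 4.2e-13, but adjusted p = 0.42 with an estimated correlation). The log2 slope on log10 exon length was -0.102 ± 0.045 at this dose and 0.035 ± 0.033 in the vehicle (SD, n = 3). This list was not tested with that trend taken out. The medium dose gave 263 called genes and the low dose 1395, and both counts depended on single libraries. The medium count was 131 without vehicle replicate 1, 161 without vehicle replicate 2, 101 without medium replicate 2 and 145 without medium replicate 3, and 440 with only these 2 groups and a replicate block. The low count was 405 without vehicle replicate 1, 807 without vehicle replicate 2, 444 without low replicate 1, 825 without low replicate 3 and 924 with a trend in exon length taken out.

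Dried ginger at its high dose raised aryl hydrocarbon receptor targets and inflammatory genes along with the ATF4 and NRF2 targets. Of 12 receptor targets 10 rose (11 adjusted over the list alone), with a median log2 fold change of 0.68 (adjusted p = 3.3e-32). CYP1B1, an oxidase of estrogens and foreign compounds (ENSG00000138061, chromosome 2, 38066973 to 38109902), rose from 167 ± 1.05 to 324 ± 8.64 CPM (mean ± SD, n = 3; log2 fold change 0.95 ± 0.04 (SE), adjusted p = 9.9e-28). CYP1A1 (1.82 ± 0.26), ALDH1A3 (0.82 ± 0.02) and TIPARP (0.79 ± 0.05) rose too. Of 32 NF-kB cytokine, chemokine and feedback genes, 13 rose and 1 fell (18 and 1 adjusted over the list alone, list test adjusted p = 3.3e-09), among them the chemokine CXCL8 (1.24 ± 0.11, adjusted p = 2.0e-13). ATF4 targets rose in 32 of 35 cases and fell in 1 (32 and 1 adjusted over the list alone; median 0.41, adjusted p = 1.1e-47), with ASNS at 0.71 ± 0.03 and TRIB3 at 0.73 ± 0.05. NRF2 targets rose in 22 of 29 cases (22 adjusted over the list alone, list test adjusted p = 1.9e-27), with NQO1 at 0.79 ± 0.03. NPTX1 (1.37 ± 0.13), the thrombin receptor THBD (1.24 ± 0.08) and IGFBP1 (1.18 ± 0.06) had large rises. YAP and SRF targets fell in 17 of 25 cases (1 rose, 20 and 1 adjusted over the list alone, list test adjusted p = 6.1e-21), collagens and matrix genes in 17 of 32 (1 rose, 20 and 1 adjusted over the list alone, list test adjusted p = 2.1e-13) and replication genes in 25 of 36 (29 adjusted over the list alone, list test adjusted p = 7.3e-18). LGR6 (-1.21 ± 0.15) and PTPRB (-0.96 ± 0.09), a receptor phosphatase best known from endothelium, fell as well. Of the called genes 1364 were higher and 1617 lower.

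At the lower doses of dried ginger the aryl hydrocarbon receptor targets stayed higher than in the vehicle. At the medium dose 6 of 12 rose (8 adjusted over the list alone; median 0.22, adjusted p = 7.2e-27), with ALDH1A3 at 0.39 ± 0.02 (adjusted p = 9.6e-21) and CYP1B1 at 0.32 ± 0.04. Folding genes rose in 12 of 24 cases (14 adjusted over the list alone, list test adjusted p = 3.0e-25), with HSPA5 at 0.29 ± 0.03. At the low dose the receptor list had a median of 0.08 (adjusted p = 0.0017), and ALDH1A3 was its called member at 0.13 ± 0.02 (adjusted p = 0.0012, 2 members rising adjusted over the list alone). Under other settings the adjusted p of ALDH1A3 reached 0.1, with only the 2 groups in the fit. CYP1B1 was 0.89 ± 0.04 higher at the high than at the low dose and CXCL8 1.52 ± 0.11, among 2319 genes that differed. The medium dose gave 123 called genes, 61 without vehicle replicate 1, 72 without medium replicate 1, 79 without medium replicate 3, 59 with only the 2 groups in the fit and 293 with no filter. The low dose gave 9, which fell to 3 and 1 without vehicle replicates 1 and 2 and to 5, 1 and 2 without low replicates 1, 2 and 3. The low count was 2 with only the 2 groups in the fit, 28 by DESeq2 and 213 with no filter.

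Dried and fresh ginger were compared directly at equal doses. At 500 µg/mL the ATF4 response was weaker and the inflammatory and aryl hydrocarbon receptor responses were stronger under dried ginger. Of 35 ATF4 targets 26 were lower under dried ginger and 1 was higher (28 and 1 adjusted over the list alone; median -0.23, adjusted p = 2.9e-81). ASNS stood at 80.3 ± 1.31 CPM under dried and 119.8 ± 2.68 CPM under fresh ginger (mean ± SD, n = 3; log2 fold change -0.58 ± 0.03 (SE), adjusted p = 3.4e-21). ADM2 (-0.82 ± 0.11), GDF15 (-0.73 ± 0.08) and TRIB3 (-0.65 ± 0.04) were lower as well. Of 32 NF-kB genes 13 were higher under dried ginger (16 adjusted over the list alone, list test adjusted p = 9.0e-26), CXCL8 by 0.97 ± 0.10 (adjusted p = 6.7e-10). SERPINB2, an inhibitor of plasminogen activators, was higher by 0.88 ± 0.06. Of 12 receptor targets 5 were higher and 1 lower (6 and 1 adjusted over the list alone, list test adjusted p = 2.4e-12), with ALDH1A3 at 0.40 ± 0.02 and CYP1B1 at 0.29 ± 0.03. Hypoxia and glycolysis genes were lower in 10 of 37 cases and higher in 1 (22 and 1 adjusted over the list alone, list test adjusted p = 1.4e-14). In all, 105 genes were higher and 145 lower at the high dose, and the count of 250 was 165 without high-dose fresh ginger replicate 1 and 154 with only the 2 groups in the fit.

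At the medium dose 12 genes differed between dried and fresh ginger, and the ATF4 list was lower under dried ginger (median -0.08, 2 members called, 16 lower and 1 higher adjusted over the list alone, adjusted p = 3.2e-17). ALDH1A3 was higher by 0.17 ± 0.02 (adjusted p = 4.9e-07, 0.056 with only the 2 groups in the fit). The aryl hydrocarbon receptor list was higher as well (median 0.08, 1 member called, 3 higher and 1 lower adjusted over the list alone, adjusted p = 1.7e-07). The 12 genes became 5, 7 and 4 without medium-dose dried ginger replicates 1, 2 and 3, 4 and 7 without medium-dose fresh ginger replicates 2 and 3, 3 with only the 2 groups and 25 by DESeq2. With no filter 98 genes were called at the medium dose. Low doses differed in 49 genes, and in 351 with no filter. Hypoxia and glycolysis genes had a median of -0.04, with 2 of 37 lower under dried ginger (3 adjusted over the list alone, list test adjusted p = 6.2e-06, and adjusted p = 0.053 with an estimated correlation). The 49 fell to 0 without low-dose fresh ginger replicates 1 or 3 or dried ginger replicates 2 or 3, to 3 without dried ginger replicate 1 and rose to 226 without fresh ginger replicate 2. With all libraries 1899 genes had an unadjusted p under 0.05, and the called genes were 97 by DESeq2, 12 with the trend in exon length taken out and 8 with only the 2 groups in the fit.

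Pinellia at its high dose raised the NF-kB inflammatory genes, with cytokines and chemokines at the top, and lowered collagens and other matrix genes. Of 32 tested NF-kB cytokine, chemokine and feedback genes 30 rose (32 adjusted over the list alone), with a median log2 fold change of 1.75 (adjusted p = 2.6e-104). CXCL8, a chemokine that draws neutrophils (ENSG00000169429, chromosome 4, 73740506 to 73743716), rose from 5.33 ± 0.641 to 209 ± 10.7 CPM (mean ± SD, n = 3), a log2 fold change of 5.29 ± 0.08 (SE; adjusted p = 1.0e-47). The cytokines IL6 (2.80 ± 0.10) and IL1B (2.42 ± 0.11), the mitochondrial superoxide dismutase SOD2 (2.60 ± 0.03, adjusted p = 3.0e-50), the early response gene IER3 (2.50 ± 0.14) and the adhesion molecule ICAM1 (2.06 ± 0.04) rose as well. NFKBIA, the inhibitor that NF-kB itself induces, rose by 1.57 ± 0.04. Immediate early genes rose in 15 of 31 cases and fell in 4 (16 and 4 adjusted over the list alone, list test adjusted p = 6.5e-06). Matrix metalloproteinases and other proteases rose in 11 of 18 and fell in 3 (11 and 3 adjusted over the list alone, list test adjusted p = 8.1e-06), with the plasminogen activator PLAU at 0.84 ± 0.04. Of 32 collagens and matrix genes 20 fell and 1 rose (21 and 2 adjusted over the list alone; median -0.16, adjusted p = 2.7e-11), COL5A1 by -0.37 ± 0.04 and COL1A2 by -0.31 ± 0.03. Folding genes fell in 11 of 24 cases and rose in 3 (11 and 3 adjusted over the list alone, list test adjusted p = 2.7e-04), with HSPA5 at -0.33 ± 0.03. Called genes numbered 1634 higher and 1534 lower, and 1951 in all with only the 2 groups in the fit.

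The NF-kB genes also rose at the lower doses of Pinellia. Of 32 members 25 rose at the medium dose (28 adjusted over the list alone; median 0.66, adjusted p = 3.0e-98), with CXCL8 at 1.96 ± 0.10 (adjusted p = 9.7e-22), SOD2 at 1.16 ± 0.03 and IL6 at 1.09 ± 0.12. At the low dose 6 rose (12 adjusted over the list alone; median 0.21, adjusted p = 1.0e-17), with SOD2 at 0.35 ± 0.03 (adjusted p = 1.3e-09). CXCL8 at the low dose, at 0.49 ± 0.12, did not pass the test (adjusted p = 0.059); it passed in 5 of 14 other settings, with adjusted p = 2.3e-04 at the lowest. Between the high and low doses 2549 genes differed, 1426 with only the 2 groups in the fit, and CXCL8 was higher by 4.80 ± 0.07 at the high dose. The medium dose gave 247 called genes, and 107, 148, 134 and 128 without vehicle replicates 1 and 2 and medium replicates 2 and 3. With only the 2 groups in the fit the medium count was 130, and with no filter 499. The low dose gave 25, which became 3 and 4 without vehicle replicates 1 and 2 and 58, 6 and 3 without low replicates 1, 2 and 3. The low count was 40 with only the 2 groups, 46 by DESeq2, 81 with the replicate block and 243 with no filter.

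Scutellaria at its high dose changed the genes of stress, lipid and inflammatory programs upward and those of cell division and collagen matrix downward. Of 35 ATF4 targets 34 rose (34 adjusted over the list alone), with a mean log2 fold change of 1.79 (adjusted p = 6.0e-37). GDF15, a cytokine of cell stress (ENSG00000130513, chromosome 19, 18374731 to 18389176), rose from 3.88 ± 0.452 to 188 ± 11.8 CPM (mean ± SD, n = 3; log2 fold change 5.59 ± 0.07 (SE), adjusted p = 4.5e-52). HMOX1, which breaks down haem, rose from 55.3 ± 1.25 to 1210.3 ± 71.3 CPM (log2 fold change 4.45 ± 0.05). Of 29 NRF2 targets 24 rose and 2 fell (25 and 2 adjusted over the list alone, list test adjusted p = 1.4e-12). Cholesterol genes rose in 22 of 26 cases and fell in 1 (22 and 1 adjusted over the list alone, list test adjusted p = 1.8e-08). Immediate early genes rose in 25 of 31 (3 fell; 25 and 3 adjusted over the list alone, list test adjusted p = 2.8e-15), with ATF3 at 4.10 ± 0.11. NF-kB genes rose in 27 of 32 (3 fell; 27 and 3 adjusted over the list alone, list test adjusted p = 1.3e-09), with CXCL8 at 3.60 ± 0.08. Mitosis genes fell in 34 of 35 cases (34 adjusted over the list alone; median -0.72, adjusted p = 4.5e-24), with the kinesin KIF20A at -1.58 ± 0.04. Collagens and matrix genes fell in 29 of 32 (1 rose; 29 and 1 adjusted over the list alone; median -0.76, adjusted p = 4.6e-19), and COL1A1, a chain of type I collagen, fell from 3258 ± 80.6 to 701 ± 35.3 CPM. Also lower were VAV3, a guanine nucleotide exchange factor, which fell from 19.2 ± 0.467 to 1.21 ± 0.210 CPM, and LGR6 (-3.53 ± 0.21). Of the called genes 5328 were higher and 5008 lower, 1603 of them by more than 2-fold.

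The lower doses of Scutellaria lowered aryl hydrocarbon receptor targets. At the low dose 8 of 12 fell (11 adjusted over the list alone; median -0.60, adjusted p = 2.7e-49). At the medium dose 6 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.50, adjusted p = 3.4e-16). CYP1B1 stood at 167 ± 1.05 CPM in the vehicle and at 68.8 ± 3.55, 73.5 ± 3.64 and 55.7 ± 4.68 CPM from the low to the high dose (mean ± SD, n = 3; adjusted p at the low dose = 2.4e-31). AHRR, the repressor that the receptor induces, fell by 0.99 at the low dose and 0.94 at the medium dose (log2). TIPARP, another feedback gene of the receptor, fell at the low dose (-0.88 ± 0.06) and was higher at the high than at the low dose (1.00 ± 0.05). At the high dose the list had 6 risen and 5 fallen members (6 and 5 adjusted over the list alone; median -0.23, mean -0.02 and an upward direction of the test, adjusted p = 0.73). ATF4 targets rose in 30 of 35 cases at the medium dose and fell in 2 (32 and 2 adjusted over the list alone, list test adjusted p = 2.3e-67), with TRIB3 at 1.17 ± 0.05. HMOX1 was higher by 4.39 ± 0.05 at the high than at the low dose, among 10201 genes that differed. The medium dose gave 1484 called genes, 854 without vehicle replicate 1 and 900 without medium replicate 3, and the low dose 477, which became 252 without vehicle replicate 1 and 292 without low replicate 3.

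Coptis at its high dose gave the widest change, with stress, folding and lysosome genes and cytosolic ribosomal proteins higher and cell division genes lower. Of 35 ATF4 targets 33 rose and 1 fell (33 and 1 adjusted over the list alone; median 1.73, adjusted p = 5.6e-21). GDF15 rose from 3.88 ± 0.452 to 693 ± 16.9 CPM (mean ± SD, n = 3), a log2 fold change of 7.47 ± 0.07 (SE; adjusted p = 8.2e-59). TRIB3, a pseudokinase that damps AKT (4.92 ± 0.04), ATF3 (5.16 ± 0.10), DDIT3 (4.74 ± 0.06) and IRS2 (4.39 ± 0.07) rose as well. All 24 folding genes rose (24 adjusted over the list alone; median 1.04, adjusted p = 2.5e-14), HSPA5 by 2.33 ± 0.03. Autophagy and lysosome genes rose in 28 of 31 cases and fell in 1 (28 and 1 adjusted over the list alone, list test adjusted p = 1.6e-12), with the autophagy receptor SQSTM1 at 1.65 ± 0.03. All 61 cytosolic ribosomal protein genes rose (61 adjusted over the list alone; median 0.64; adjusted p = 6.3e-15, but adjusted p = 0.2 with an estimated correlation). The log2 slope on log10 exon length was -0.080 ± 0.007 at this dose and 0.035 ± 0.033 in the vehicle (SD, n = 3). The ribosomal protein list was not tested with that trend taken out. Mitosis genes fell in 34 of 35 cases (34 adjusted over the list alone; median -1.01, adjusted p = 8.4e-17), with KIF20A at -3.09 ± 0.05. Replication genes fell in 31 of 36 and rose in 3 (31 and 3 adjusted over the list alone, list test adjusted p = 3.2e-10). CCN4, a secreted protein of WNT signalling (-5.22 ± 0.19), and DIO2, which activates thyroid hormone (-4.54 ± 0.08), fell as well. Of 13207 called genes 6540 were higher and 6667 lower, and 4430 changed by more than 2-fold.

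At the medium dose of Coptis 34 of 35 ATF4 targets rose (34 adjusted over the list alone; median 1.27, adjusted p = 9.1e-69), with GDF15 at 4.03 ± 0.08 and TRIB3 at 3.23 ± 0.04. All 36 replication genes fell (36 adjusted over the list alone; median -0.58, adjusted p = 6.2e-37). YAP and SRF targets rose in 21 of 25 cases and fell in 1 (22 and 1 adjusted over the list alone, list test adjusted p = 5.3e-18). TXNIP, a glucose-regulated arrestin, fell (-2.89 ± 0.13, adjusted p = 5.1e-26), and it fell at the low dose too (-0.81 ± 0.09, adjusted p = 4.5e-08). Low-dose Coptis raised 11 ATF4 targets (20 rose and 2 fell adjusted over the list alone, list test adjusted p = 4.5e-18), with ASNS at 0.22 ± 0.03 and TRIB3 at 0.29 ± 0.05. Replication genes had a median of -0.10 at the low dose (2 fell, 9 adjusted over the list alone, list test adjusted p = 1.5e-13). GDF15 was higher by 6.93 ± 0.06 at the high than at the low dose, among 13315 genes that differed. The medium dose gave 7241 called genes. The low dose gave 120, and 45, 56 and 78 without vehicle replicates 1, 2 and 3. Without low replicates 1, 2 and 3 the low count was 78, 52 and 64. It was 193 by DESeq2, 199 with the replicate block and 336 with no filter.

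Transcripts of the mitochondrial ribosome rose at every dose of Coptis while most mitochondrial mRNAs did not. MT-RNR1 and MT-RNR2, the small and large mitochondrial ribosomal RNAs, were chosen after their values were seen. MT-RNR1 (mitochondrial genome, 648 to 1601) stood at 684 ± 11.1 CPM in the vehicle and at 2875 ± 179.5, 19156 ± 935 and 8236 ± 219 CPM at the low, medium and high doses (mean ± SD, n = 3). Its log2 fold changes were 2.07, 4.81 and 3.59, each ± 0.05 (SE), with adjusted p = 1.5e-37, 1.6e-53 and 1.4e-49. MT-RNR2 (1671 to 3229) rose by 1.17, 3.10 and 1.79, with adjusted p = 1.3e-26, 2.1e-46 and 2.1e-37. Between the high and low doses, which share a code set, MT-RNR1 differed by 1.52 (adjusted p = 3.3e-34) and MT-RNR2 by 0.62 (adjusted p = 6.8e-18). Of 13 mitochondrial mRNAs 10 fell at the medium dose (11 adjusted over the list alone; median -0.62; adjusted p = 2.5e-06, but adjusted p = 0.13 with an estimated correlation and 0.051 with no filter). Of the mRNAs, 2 rose and 5 fell at the low dose (2 and 8 adjusted over the list alone, list test adjusted p = 2.9e-06, but adjusted p = 0.19 with an estimated correlation). At the high dose 3 rose and 4 fell (2 and 4 adjusted over the list alone, list test adjusted p = 0.82). Mitochondrial genes held 5.16% ± 0.19 of the counts in the vehicle, 11.08% ± 0.50 at the medium and 6.33% ± 0.45 at the high dose (SD, n = 3).

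**Figure D2:**
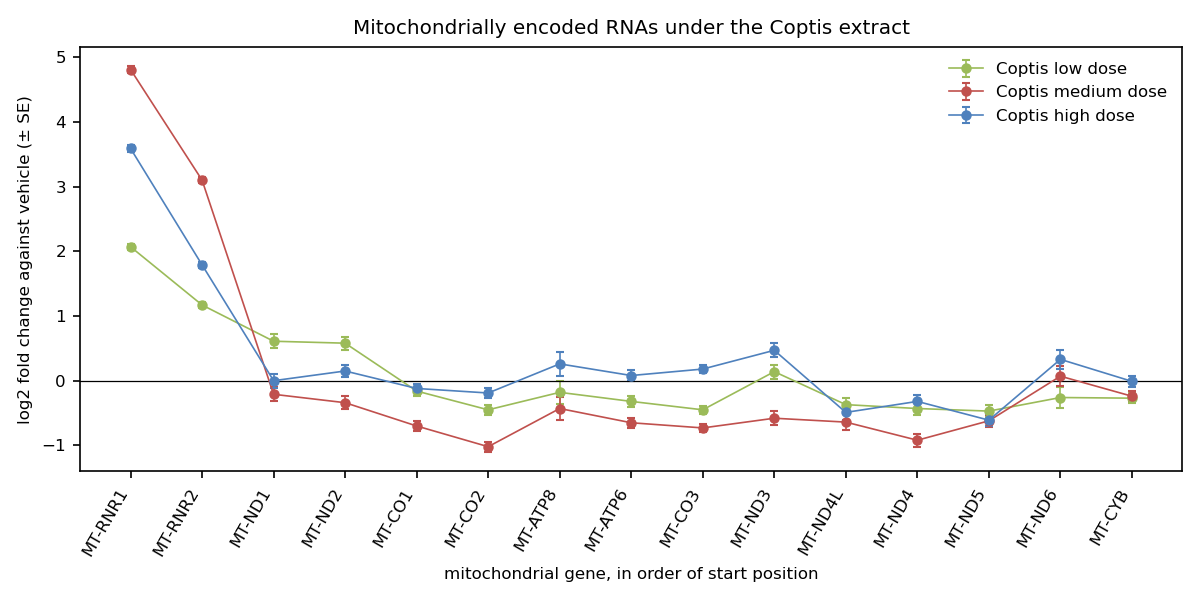
Log2 fold change against the vehicle (vertical axis; points with SE bars, joined by lines) of the mitochondrial genes in order of start position (horizontal axis) at the low, medium and high doses of Coptis, 3 libraries per group. MT-RNR1 rose by 4.81 and MT-RNR2 by 3.10 at the medium dose, while the mRNA genes lay far lower.

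Jujube at its high dose raised TXNIP, mitosis genes and immediate early genes, and lowered folding and metallothionein genes. TXNIP, an arrestin that limits glucose uptake (ENSG00000265972, chromosome 1, 145992435 to 145996600), rose from 9.62 ± 0.385 to 202 ± 1.91 CPM (mean ± SD, n = 3), a log2 fold change of 4.39 ± 0.06 (SE; adjusted p = 2.0e-49). Its relative ARRDC4 rose by 2.15 ± 0.08 (adjusted p = 7.1e-28). EGR1, an immediate early transcription factor, rose by 0.92 ± 0.08, with 12 of 31 immediate early genes rising and 1 falling (13 and 3 adjusted over the list alone, list test adjusted p = 2.0e-04). Mitosis genes rose in 19 of 35 cases (23 rose and 1 fell adjusted over the list alone; median 0.12, adjusted p = 2.5e-10), with the cyclin CCNA2 at 0.28 ± 0.04. Aryl hydrocarbon receptor targets rose in 7 of 12 and fell in 1 (9 and 1 adjusted over the list alone, list test adjusted p = 2.7e-09). Folding genes fell in 14 of 24 cases and rose in 1 (15 and 2 adjusted over the list alone; median -0.17, adjusted p = 4.4e-13), with HSPA5 at -0.45 ± 0.03. Metallothionein and zinc export genes fell in 4 of 5 (4 adjusted over the list alone, list test adjusted p = 1.2e-06), with MT1E at -1.23 ± 0.11. YAP and SRF targets fell in 15 of 25 and rose in 3 (17 and 3 adjusted over the list alone, list test adjusted p = 9.9e-11). FAM13B (-1.22 ± 0.04, adjusted p = 3.6e-29), TNFSF15 (-1.09 ± 0.10) and GDF15 (-1.03 ± 0.14) fell as well. Called genes numbered 1437 higher and 1598 lower.

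The lower doses of jujube changed few genes. The medium dose gave 64 called genes, among them TXNIP (0.54 ± 0.08, adjusted p = 1.4e-04) and FAM13B (-0.22 ± 0.04, adjusted p = 0.0021). At the low dose TXNIP stood at 10.2 ± 0.345 CPM against 9.62 ± 0.385 CPM in the vehicle and did not pass the test (log2 fold change 0.09 ± 0.08 (SE), adjusted p = 0.83). The 2 genes called at the low dose, both chosen after their values were seen, were GALT, an enzyme of galactose use (log2 fold change 0.42, adjusted p = 0.0048), and ATXN1 (-0.18, adjusted p = 0.031). GALT was called higher than in the vehicle under wortmannin (0.33) and every other extract group as well, so this call is not particular to jujube. Between the high and low doses, 2679 genes differed. TXNIP was higher by 4.30 ± 0.06 and ARRDC4 by 2.28 ± 0.08 at the high dose, and FAM13B was lower (-1.09 ± 0.04). Mitosis genes were higher at the high than at the low dose in 25 of 35 cases (27 adjusted over the list alone, list test adjusted p = 5.3e-18). The medium count of 64 was 18, 38 and 31 without vehicle replicates 1, 2 and 3, and 24, 39 and 19 without medium replicates 1, 2 and 3. It was 183 with only the 2 groups in the fit, 114 by DESeq2, 128 with the replicate block and 302 with no filter. At the low dose the 2 called genes became 1 (GALT) without vehicle replicate 1 and 0 without vehicle replicate 2 or low replicates 2 or 3. There 1465 genes had an unadjusted p under 0.05. DESeq2 called 18 genes at that dose, the replicate block 14 and the fit with no filter 164.

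**Figure D3:**
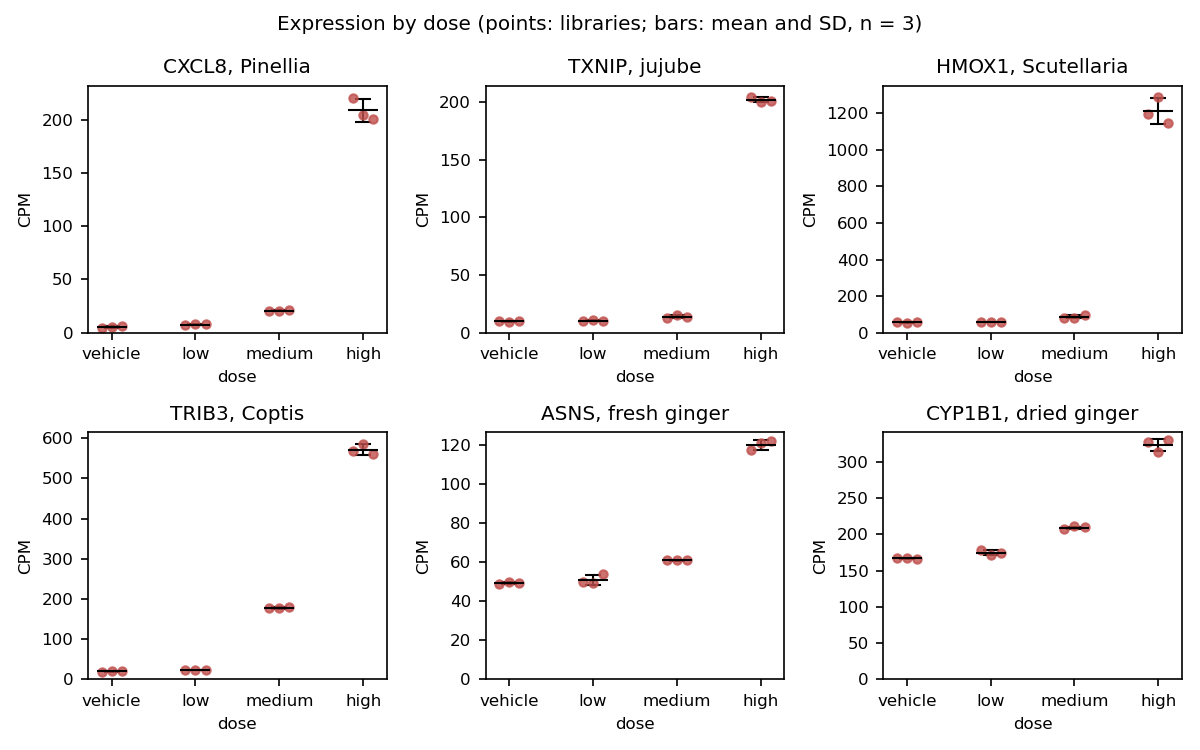
CPM (vertical axis, linear from 0) of 6 genes in the vehicle and at the low, medium and high doses (horizontal axis) of 1 extract each, with points for libraries and bars for mean and SD (n = 3). CXCL8 reached 209 CPM at the high dose of Pinellia and TXNIP 202 CPM at that of jujube, from 5.33 and 9.62 CPM in the vehicle.

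Whether the extracts resemble the positive control was examined across the 17569 tested genes, which are not independent replicates. Fold changes at the high doses correlated with those of wortmannin at a Pearson r of 0.45 for fresh ginger, 0.49 for dried ginger, 0.34 for Pinellia, 0.21 for Scutellaria, 0.05 for Coptis and 0.46 for jujube. Each comparison used the same 3 vehicle libraries, and unchanged groups simulated with those libraries gave a mean r between 0.52 and 0.54, with single simulations between 0.45 and 0.62. Covariance with wortmannin exceeded the simulated one for 5 extracts, by 0.035 for fresh ginger, 0.041 for dried ginger, 0.024 for Pinellia, 0.025 for Scutellaria and 0.037 for jujube, and for Coptis it lay below by 0.014. The simulated covariance is a mean over 8 simulations whose spread was not computed, so these differences cannot be judged against it. Genes higher in common with wortmannin numbered 769 for fresh ginger, 705 for dried ginger, 416 for Pinellia, 1210 for Scutellaria, 1187 for Coptis and 583 for jujube. Genes lower in common numbered 1027, 895, 412, 1682, 1321 and 713 in the same order, and genes called in opposite directions 329, 293, 891, 1802, 2925 and 473. For Pinellia and Coptis more of the genes called under both moved in opposite directions than in the same direction. Independent lists of those sizes would share 277, 236, 283, 921, 1131 and 248 higher and 344, 311, 295, 963, 1283 and 307 lower genes, and the shared vehicle raises this overlap as well. FOXO targets, which rose under wortmannin, rose in 18 of 28 cases and fell in 6 under Coptis (18 and 6 adjusted over the list alone, list test adjusted p = 4.5e-04), and rose in 18 and fell in 5 under Scutellaria (19 and 5 adjusted over the list alone, list test adjusted p = 1.5e-05). Of all 17569 tested genes, 6540 were called higher and 6667 lower under Coptis, and 5328 and 5008 under Scutellaria. These extracts had the lowest r, and counts of this list for the other extracts are not given here. All 6 high doses had 93 genes called higher and 168 called lower in common, where independent lists would share 0.1 and 0.1 and the shared vehicle again adds to the overlap. Across all 18 extract groups 1 gene was called in the same direction, GALT, chosen after its values were seen, with log2 fold changes of 0.26 to 0.48. It was also called higher under wortmannin (0.33, adjusted p = 1.7e-04), so it differed from the vehicle in every treated group. DESeq2 gave 0 such genes and 17 had an unadjusted p under 0.05 throughout, while leaving out any of the 3 vehicle libraries also gave 0. Among those 17, HES7 (log2 fold changes of 2.47 to 7.85), HES4 (1.05 to 2.86) and IDUA (0.53 to 1.13) had larger values than GALT in every extract group. HES7 and HES4 averaged under 1 CPM, and all of these genes were chosen after their values were seen. A shift of the vehicle libraries, including one from solvent, cannot be told apart from treatment here.

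Markers of other cell types were tested beside these lists. Of 7 tested epithelial and hepatocyte markers 2 fell under the high dose of fresh ginger (3 adjusted over the list alone; median -0.33, adjusted p = 0.0066), 2 under dried ginger (2 adjusted over the list alone; median -0.30, adjusted p = 0.013) and 4 under Scutellaria (4 adjusted over the list alone; median -0.78, adjusted p = 0.032). With no filter on low counts these adjusted p were 0.072, 0.11 and 0.093. The keratin KRT18, which is also among the YAP and SRF targets, fell at all 6 high doses, under fresh (-0.65 ± 0.04) and dried ginger (-0.74 ± 0.04), Pinellia (-0.44 ± 0.04), Scutellaria (-1.62 ± 0.04), Coptis (-0.39 ± 0.04) and jujube (-0.24 ± 0.04). Neuron markers fell in 3 of 6 cases under the high dose of jujube (3 adjusted over the list alone; median -0.20, adjusted p = 0.0027). Endothelial markers passed the test under none of the high doses or wortmannin by camera, with adjusted p between 0.14 under Pinellia and 0.94 under fresh ginger. Astrocyte and glioma markers rose in 6 of 13 cases and fell in 1 under wortmannin (6 and 1 adjusted over the list alone, list test adjusted p = 0.017). They fell in 6 and rose in 2 under Pinellia (6 and 2 adjusted over the list alone, list test adjusted p = 0.012). Under Scutellaria they fell in 7 and rose in 3 (7 and 3 adjusted over the list alone, list test adjusted p = 0.024), with a median of -0.22 but a mean of 0.00. Of the 16 immune markers 4 had enough counts to be tested, too few for a list test, and the others averaged at most 0.112 CPM over library totals.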

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

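The tests of the code sets for TXNIP and of the Coptis dose were chosen only after the results they measure had been seen. A rule added after the values were seen left open any explanation whose value lay within its spread of a bound. It did the same where most genes tested averaged under 1 CPM. Dried and fresh ginger at equal dose differed by a direct test in 250 genes at the high dose, 12 at the medium dose and 49 at the low dose, which is what drew attention to them. ASNS at the high dose stood at 80.3 ± 1.31 CPM under dried and 119.8 ± 2.68 CPM under fresh ginger (mean ± SD, n = 3), and CXCL8 was higher under dried ginger by 0.97 ± 0.10 (log2, SE). The count of 250 was 165 without high-dose fresh ginger replicate 1. The count of 12 was 4 at the lowest with 1 library left out, without medium-dose dried ginger replicate 3 or fresh ginger replicate 2. The count of 49 fell to 0 without low-dose fresh ginger replicates 1 or 3 or dried ginger replicates 2 or 3, and rose to 226 without fresh ginger replicate 2.

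Each comparison sets 3 libraries against 3, and the 10 splits of 6 libraries are too few for a share under 0.05. With edgeR on those 6 libraries, the real split of wortmannin and vehicle called 6745 genes and the highest other split 0. For the high, medium and low doses against the vehicle, the real and highest other counts were 3312 and 0, 253 and 6, and 998 and 2 under fresh ginger, and 2555 and 1, 59 and 6, and 2 and 4 under dried ginger. They were 1951 and 0, 130 and 2, and 40 and 3 under Pinellia, and 9793 and 0, 1449 and 1, and 353 and 3 under Scutellaria. Under Coptis they were 12535 and 0, 7213 and 0, and 175 and 3, and under jujube 3378 and 0, 183 and 4, and 1 and 1. For high against low dose they were 3570 and 2 for fresh ginger, 1800 and 0 for dried ginger, 1426 and 0 for Pinellia, 9534 and 0 for Scutellaria, 12684 and 0 for Coptis and 2863 and 1 for jujube. For dried against fresh ginger they were 154 and 5, 3 and 4, and 8 and 9. The number of the 10 splits with as many called genes was 1 except for 4 comparisons. It was 2 for dried ginger at the low dose, 3 for jujube at the low dose, and 2 and 3 for dried against fresh ginger at the medium and low doses.

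Fresh ginger called 1395 genes at its low dose and 263 at its medium dose. A single library of the low dose does not account for the order of these counts, since at least 444 genes were called whichever of the 3 was left out. The size of the difference did depend on 1 library, as the low count fell from 1395 to 444 without low replicate 1. A trend with exon length does not account for the order either, since 924 genes were called after it was taken out, against 276 at the medium dose. The genes lower at the low dose were long, with a median exon length of 7676 bases against 4335 for all genes, so such a trend may add to the count. Over the genes called at the low dose the change at the medium dose was a median of 0.50 ± 0.08 (SD over left-out medium libraries) of that at the low dose, on the bound of 0.5 set in advance, while the high dose of fresh ginger gave 0.41 and low-dose dried ginger, which shares the vehicle, 0.47. An effect of the extract itself and a shift of the vehicle therefore cannot be told apart by this ratio, and without vehicle replicate 1 the counts were 405 and 131.

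MT-RNR1 and MT-RNR2 rose at every dose of Coptis, most at the medium dose. Reads moved from nuclear copies do not account for it, because the sum of both genes and their nuclear copies rose 9.0-fold, from 9541 ± 389 to 86304 ± 4373 CPM (mean ± SD, n = 3) over library totals without the TMM factors, a scale on which values are not comparable with the CPM of single genes given elsewhere. A dependence on the Coptis dose is consistent with both genes being higher at the high than at the low dose within 1 code set, by at least a log2 of 0.62, although the medium dose exceeded the high dose. Carry-over of RNA without a poly(A) tail stays open. The median log2 fold change of 14 other small RNAs was -0.41. By the bound of 0.5 set in advance, taken alone, this would count against carry-over. But 12 of them averaged under 1 CPM, too near the floor to decide, a criterion added after the values were seen. Whether the extract changes mitochondrial transcription or the decay of the ribosomal RNAs was not tested.

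TXNIP and ARRDC4 rose together under the high dose of jujube. A difference between code sets does not account for it, as both were higher at the high than at the low dose, which share a set, by at least a log2 of 2.28. Both genes are known to answer glucose, and the medium used here holds galactose in its place, so sugar in the extract is a candidate explanation. The 5 other tested genes known to answer glucose had a median of 0.19 ± 0.16 (SD), with KLF10, HK2 and PFKFB3 called higher. This lies under the bound of 0.25 set in advance, which taken alone would count against the explanation. The margin is smaller than the spread, a criterion added after the value was seen. That spread includes RGS16 at 0.50 ± 1.06 (SE; adjusted p = 0.81), while the others lay between 0.11 and 0.20. With KLF10, HK2 and PFKFB3 called higher, the explanation stays open, and HK2 and PFKFB3 are also hypoxia genes.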

How the results depend on the processing

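Leaving out mitochondrial genes, taking out a trend with exon length and the block with only the 2 groups of medium-dose fresh ginger and vehicle were tests chosen after the data had been seen. RLE size factors, the stricter filter and leaving out mitochondrial genes kept all 28 counts of called genes within 1.5 times, and leaving out a library did so for every high dose against the vehicle and every high against low dose. The causes of the changes below were not tested, except that fits with only 2 groups or with a library left out hold fewer samples. No filter gave 293 and 213 called genes for medium and low dried ginger, 499 and 243 for medium and low Pinellia, 336 for low Coptis, 302 and 164 for medium and low jujube, and 98 and 351 for dried against fresh ginger at the medium and low doses. Only the 2 groups gave 59 and 2 for medium and low dried ginger, 1951, 130 and 40 for high, medium and low Pinellia, 183 and 1 for medium and low jujube, 1426 for high against low Pinellia, and 154, 3 and 8 for dried against fresh ginger. DESeq2 gave 28 for low dried ginger, 46 for low Pinellia, 193 for low Coptis, 114 and 18 for medium and low jujube, 25 and 97 for dried against fresh ginger at the medium and low doses, and 0 in place of 1 gene called in every extract group. The replicate block gave 81 for low Pinellia, 199 for low Coptis, and 128 and 14 for medium and low jujube, and with only the 2 groups 440 for medium fresh ginger. With the trend in exon length taken out, low fresh ginger gave 924, low dried ginger 14, and dried against fresh ginger at the low dose 12.

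Leaving out 1 library in turn gave ranges of 5672 to 5756 for wortmannin, 2567 to 2991, 101 to 258 and 405 to 1430 for high, medium and low fresh ginger, 2183 to 2622, 61 to 96 and 1 to 12 for dried ginger, 2348 to 2826, 107 to 254 and 3 to 58 for Pinellia, 9640 to 9873, 854 to 1243 and 252 to 408 for Scutellaria, 12784 to 12908, 6425 to 6676 and 45 to 78 for Coptis, and 2195 to 2485, 18 to 39 and 0 to 3 for jujube. For dried against fresh ginger they were 165 to 202, 4 to 10 and 0 to 226, and for genes called in every extract group 0. The correlation with wortmannin was 0.41, 0.40, 0.22, 0.15, 0.01 and 0.44 with the stricter filter, for fresh ginger, dried ginger, Pinellia, Scutellaria, Coptis and jujube. Without 1 vehicle replicate it was 0.55 to 0.59, 0.58 to 0.62, 0.47 to 0.50, 0.31 to 0.34, 0.13 to 0.15 and 0.56 to 0.60. Of 388 list calls 388 held with RLE factors, 224 with an estimated correlation, 347 with no filter and 370 with only the 2 groups, while 14 were lost with the stricter filter and 1 with the replicate block. With 1 library left out 2206 of the list results held and 120 were lost. The ribosomal protein list turned from lower to higher in dried ginger at the high against the low dose without high replicate 3 (median -0.08 to 0.02 over left-out libraries, adjusted p = 0.26 at 0.02) and in dried against fresh ginger at the medium dose without medium-dose dried ginger replicate 2 (median -0.08 to 0.02, adjusted p = 0.72 at 0.02). Of 1001 values of genes in a comparison, none changed direction, and 98 changed their call under at least 1 setting, as did 175 of the 388 list calls. Calls of genes were lost in 8 cases by DESeq2, 2 with RLE factors, 18 with no filter, 26 with only the 2 groups, 8 with the trend in exon length taken out, and 259 of the fits that left out 1 library, where 5746 kept theirs. Many of these genes were chosen for large changes or small p in these data, so their stability does not carry over to called genes in general. A planned test by limma on log2 values was not run, since the values are counts. Depth limits genes under about 0.091 to 0.149 CPM, the level that 0 counts in a library allow.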

Other observations

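The test of position along the mitochondrial genome was chosen after the values had been seen. The changes in this paragraph are those at the high doses of Scutellaria and Coptis against the vehicle. Fatty acid synthesis genes rose in 12 of 15 cases and fell in 3 under Scutellaria (12 and 3 adjusted over the list alone; median 0.60, adjusted p = 7.4e-06), with the desaturase SCD at 2.12 ± 0.03 (log2, SE). Under Coptis the list did not pass the test (median -0.16, adjusted p = 0.093), with 4 risen and 8 fallen members (5 and 8 adjusted over the list alone), among them the elongase ELOVL6 (-2.08 ± 0.05). ABCA1, which exports cholesterol, rose by 3.02 ± 0.04 under Scutellaria and 2.17 ± 0.04 under Coptis. Interferon-stimulated genes fell in 21 of 33 cases and rose in 3 under Scutellaria (21 and 3 adjusted over the list alone, list test adjusted p = 3.3e-04), with IFIT1 at -1.92 ± 0.14 and GBP1 at -1.79 ± 0.07. Targets of p53 rose in 15 of 26 cases and fell in 7 under Scutellaria (15 and 7 adjusted over the list alone, list test adjusted p = 5.5e-04) and rose in 16 and fell in 4 under Coptis (16 and 4 adjusted over the list alone, list test adjusted p = 0.0011). TNFRSF10B, a death receptor, rose by 1.77 ± 0.03 and 2.25 ± 0.03, and SESN2, which restrains mTORC1 in amino acid shortage, by 3.21 ± 0.06 and 3.05 ± 0.07.

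Under Coptis at the high dose HSPA1A (-2.90 ± 0.08) and HSPA8 (-1.61 ± 0.03), cytosolic chaperones, fell, while HSPA1A rose under Scutellaria (1.09 ± 0.06). The heat shock list passed its test under neither, with 6 risen and 13 fallen of 25 under Coptis (6 and 13 adjusted over the list alone, list test adjusted p = 0.08) and 10 and 12 under Scutellaria (10 and 12 adjusted over the list alone; median -0.06, mean 0.15, adjusted p = 0.7). MT2A, a metal-binding protein, rose under wortmannin by 1.29 ± 0.07 and MT1E fell under jujube (-1.23 ± 0.11).

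A hypothesis of this work was that Coptis lowers mitochondrial mRNAs more the farther they lie from the start of heavy strand transcription, where both ribosomal RNAs sit. Across the 12 heavy strand mRNAs, which are not independent replicates, Spearman's rho of log2 fold change on gene start was -0.57, -0.11 and -0.36 at the low, medium and high doses (Pearson's r -0.69, -0.13 and -0.29). The two-sided permutation p were 0.059, 0.732 and 0.258 with 100000 permutations, or 0.177, 0.732 and 0.387 after Benjamini-Hochberg adjustment over the 3 doses. The slope was negative at each dose, with a rho of -0.11 at the weakest, and passed the test at none, so the hypothesis may hold or not and these 12 genes do not settle it.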
